A study of Drosophila melanogaster with 2 samples.

How the data were processed

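ChIP-seq regions of an ab-eGFP line were taken from 2 biological replicates of whole embryos aged 0 to 24 hours, which form 1 group. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. Per the deposited description files, each replicate and the pool of both had a relaxed list of regions, made from the alignments of that sample and a control, and a further list of reproducible peaks was made from these by the irreproducible discovery rate (IDR) method on 2 genome builds, dm3 and dm6. The aligner, the peak caller, their versions and their thresholds were not given in the sources used here. The main results use dm6, and no coordinates were converted between builds.

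The deposited signal values are the authors' own score of each region against the control, on a scale that the deposited files do not state, and they were used to rank, filter and describe regions. The deposited −log10 q-values reached a ceiling of 3.38 in the dm6 pooled list, shared by 1213 regions, so they were not used to rank. Relaxed regions have a nearly fixed width, 384 bp in replicate 1 and 600 bp in replicate 2 on dm6, and 510 bp in the pooled list. The replicate lists on dm6 both end at 30000 regions, so their weakest members are set by that number. The reproducible list equals the 1664 strongest regions of the dm6 pooled list, and 1547 on dm3, and no column gave an IDR value per peak. Because of this, a peak can enter it through a strong signal in 1 replicate. Read depth was unknown, and intervals on shares of peaks cover counting error only. Signals of the 2 replicates were called separately and are given side by side without an SD at single peaks.

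Positions are 1-based. Genes and TSSs were taken from Ensembl release 115 (BDGP6.54, the dm6 coordinates) and sequence from the matching RefSeq assembly, on the arms 2L, 2R, 3L, 3R, 4 and X. A summit was given 1 of 7 classes in the order promoter (within 500 bp of a TSS of any gene), 5′ UTR, coding sequence, 3′ UTR, other exon, intron and intergenic. Shares were tested against the share of bases with two-sided exact binomial tests and Benjamini-Hochberg adjustment over the 7 classes, and peaks per arm against arm length in the same way over 6 arms. Replicates were matched by summits within 200 bp, with chance from 1000 circular shifts within chromosomes. Correlations and the difference of promoter and other peaks in mean log2 signal used 100000 permutations.

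A gene had a peak when a summit lay in its body or within 1 kb. The same peak can thus count for several genes, and it may lie nearer to the TSS of another gene. Each of 11 lists was set against 100000 random sets of protein-coding genes drawn from the same 10 bins of territory length, two-sided, with adjustment over the 11 lists. For the list of ribosomal proteins the unadjusted p was 2e-05, the smallest these sets can give. All listed symbols were matched to the annotation, 6 of them through older names. Members of the ribosomal and receptor lists were taken by symbol. Motifs were searched on both strands within 50 bp of each summit and in flank windows centred 300 bp to either side, with the flank given the same number of word starts as the centre. Presence was compared by exact McNemar tests, two-sided, adjusted over 7 fixed motifs and separately over all 6-mers. GC-matched positions lay on the same arm, at least 1000 bp from summits of the pooled list and within 1 percentage point of GC content.

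Lists, motifs, the tests of the comparisons and the rule for named genes were fixed before the data were examined. The rule took ab, the genes nearest to the 15 strongest peaks, the 10 genes with most peaks, the 3 members with the strongest peaks of each list and the 10 6-mers with the smallest p among those more frequent at summits. Other genes are named because of low counts or as members of a list with a peak, and these, among them RpS14a, hpo, wts, yki, Stat92E, EcR, usp, br and the neural factors without a peak, were chosen after their values were seen.

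Alternatives fixed beforehand were the dm3 lists, the 832 peaks above the median signal, the strongest 1664 regions of a single replicate, summits within 100 bp, 50% reciprocal overlap (100 shifts), whole replicate lists, promoters of 1000 and 200 bp or of protein-coding genes alone, the 10688 weakest pooled regions as background, other assignments of peaks to genes, no matching on length, merged summits, wider motif windows and GC-matched positions. Alternatives chosen after seeing the data were genes with a relaxed region as background, gene lists without promoter peaks, motifs at peaks outside or inside promoters, 50 length bins, gene lists without ab (also with replicate 2 alone), and the strongest regions of replicate 1 matched directly to those of replicate 2. Class shares, gene lists, motif windows, summit overlap and signal correlation were tested on simulated data, and the other calculations were not. With 56.8% of 1664 simulated summits in promoters, 57.6% were recovered, and 5% of 200 uniform sets were called. Of 200 random lists 4.5% were called at p below 0.05, and 95% of 200 lists whose genes with peaks were drawn 4 times as often. A 6-mer planted in simulated windows took rank 1 of all 6-mers, and the 9 other 6-mers called all shared a run of 4 bases with it. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.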

Results

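Binding of the abrupt protein (ab), a BTB and zinc-finger transcription factor of Drosophila melanogaster, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). The embryos came from a transgenic line in which ab carries a green fluorescent protein at its C-terminus, and the tag was pulled down with an antibody against it. Whole embryos of mixed sex, collected between 0 and 24 hours of age, formed a single group of 2 biological replicates. The files hold lists of enriched regions, each with a signal value from the authors' peak caller, and no read counts, so the depth of each library was unknown. On the dm6 genome build 30000 regions were listed for each replicate, 21376 for the pooled reads and 1664 as reproducible between the replicates. With 1 group, the comparisons the design implies are between replicates, between parts of the genome and between sets of genes.

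The strongest reproducible peak lay on 2L from 480881 to 481311, inside an intron of ush and 1379 bp upstream of cbt. The gene cbt encodes a zinc-finger transcription factor, and ush a partner of GATA factors. Its pooled signal was 1007, with 435.5 in replicate 1 and 551.1 in replicate 2. The next peaks stood upstream of CG14100 (3L, 19590437 to 19590816, signal 802.5) and 95 bp upstream of Chro, which encodes a chromodomain protein (3L, 22878700 to 22879083, signal 580.3). Those at Ugalt, a nucleotide sugar transporter (X, 2703722 to 2704085), and at CG1888 (2R, 9547038 to 9547385) followed with 556.4 and 534.5. The order of these peaks did not hold in each replicate: replicate 1 gave CG14100 493.7 against 435.5 at cbt, and replicate 2 gave 311.2 against 551.1. The remaining peaks among the 15 strongest lay nearest to Lk6, ph-p, CG9663, px, CG31145, CHMP2B, CG8320, CG11050, CG4004 and PNPase, with signals from 405.5 to 522.3. Lk6 is a kinase of the translation factor eIF4E, ph-p a Polycomb group protein, CHMP2B an ESCRT-III subunit and PNPase a mitochondrial RNA exonuclease. Over all 1664 peaks the median signal was 75.1 (interquartile range 60.3 to 102.6), so the peak at cbt stood far above the bulk of the list.

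Several genes collected many peaks within their bodies and 1 kb on either side. The gene sbb, which encodes a nuclear protein, held 9 peaks, the strongest on 2R from 18338313 to 18338822 with a signal of 88.0. CHES-1-like, a forkhead gene (X, 7682338 to 7709385), and kirre, which encodes an adhesion protein of muscle founder cells (X, 2740384 to 3134532), held 8 each. Counts per gene were not scaled to length, and kirre spans far more sequence than CHES-1-like. Raf, the kinase of the receptor tyrosine kinase cascade, and tara held 7 each. The genes ush, CG1677 and Hr4 held 6 each, and larp and rdx 5 each. Within Raf the strongest peak (X, 2297573 to 2297865, intronic) had signals of 126.0 in replicate 1 and 143.0 in replicate 2. The strongest within tara (3R, 16249921 to 16250430, intronic) had 18.0 and 95.7. Of 13945 protein-coding genes, 1843 (13.2%) had at least 1 reproducible peak in this territory and 314 had 2 or more.

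The replicates were compared at the reproducible peaks. Of the 1664 peaks, 1312 (78.8%) had a summit within 200 bp among the 1664 strongest regions of replicate 1, and 1175 (70.6%) among those of replicate 2. In both replicates together 891 peaks were matched in this way, or 53.5% (95% Wilson interval 51.1 to 55.9%). Shifting the peaks along the chromosomes 1000 times gave a mean of 0.263% and at most 0.781% (one-sided permutation p = 0.001, the smallest these shifts can give), but the list was drawn from the pool of the same replicates, so part of this match was fixed beforehand. Matched directly, a setting chosen after seeing the data, 881 of the 1664 strongest regions of replicate 1 (52.9%) had a summit within 200 bp among those of replicate 2, against a mean of 0.516% over shifts (permutation p = 0.001, again the smallest), and 906 (54.4%) the other way round. Of the 832 peaks above the median signal 84.4% were matched in both. Among all listed regions of the replicates, 1590 peaks (95.6%) had a match in both. The SD of the log2 difference between replicates was 0.88, or 1.84-fold. Peaks at Chro (330.6 and 250.7), Ugalt (299.0 and 272.7) and CG31145 (222.2 and 234.8) differed between replicates 1 and 2 by less than this SD. At kibra, a Hippo pathway gene, replicate 1 gave 6.42 and replicate 2 gave 75.6, and at PlexA, on chromosome 4, the values were 63.0 and 11.2, each a gap wider than the SD. Across the 1590 matched peaks, which are not independent replicates, Spearman's rho of the signals was 0.351 and Pearson's r of log2 signals was 0.44. Each had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give, and r was 0.428 without the 2 peaks farthest from the median of replicate 1. Of the matched peaks, 1237 lay within 2-fold of the median difference. Over the 8563 regions of the pooled list matched in both replicates, rho was 0.498. The reproducible list held exactly the strongest regions of the pooled list. Choosing peaks by the pooled signal of both replicates can by itself lower rho and r, so these values do not measure agreement over all regions.

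**Figure D1:**
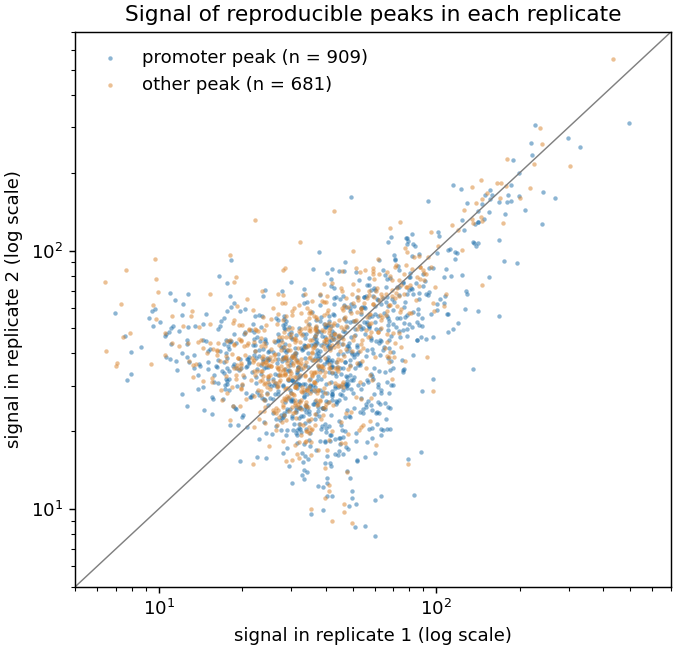
Signal of each reproducible peak in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), for promoter peaks (blue) and other peaks (orange) matched in both; the grey line marks equal signal. The strongest peaks lie near the line and the weaker ones scatter widely, with a rho of 0.351 over all 1590.

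Peaks concentrated at promoters. Summits of 941 peaks lay within 500 bp of a transcription start site (TSS), a share of 56.6% (95% Wilson interval 54.2 to 58.9%) against 13.6% of the genome, or 4.17-fold. The two-sided exact binomial p was returned as 0 at double precision. RpS27, RpL7, Chro, Ugalt and PNPase were among the genes with such a peak. By the same exact test introns held 511 peaks (30.7% against 39.5% of the genome, adjusted p = 2.0e-13), among them those at Lk6, ph-p, Trl and Hr3. Intergenic sequence held 178 (10.7% against 27.2%, exact adjusted p = 2.4e-61). Coding sequence outside promoters held 3 peaks (0.18% against 13.7%, exact adjusted p = 3.7e-100), and 3′ UTRs held 9 (0.541% against 4.43%, adjusted p = 1.9e-21). Shares in 5′ UTRs (0.541% against 0.779%) and in other exons (0.781% against 0.82%) did not pass the test against the genome, with exact binomial adjusted p of 0.383 and 1. The 7 classes divide the same peaks, so the promoter excess by itself lowers the other shares. Of the 723 peaks outside promoters 511 were intronic, so these tests do not show that introns were avoided. Relative to the nearest protein-coding TSS, 737 summits lay up to 500 bp upstream and 144 up to 500 bp downstream, so 83.7% were upstream (exact binomial p = 1.4e-96). The median summit within that range stood 85 bp upstream. Among the 10688 weakest regions of the pooled list, 21.6% were at promoters, and against them the share at reproducible peaks was 2.62-fold. Against the genome it was 6.60-fold with promoters of 200 bp and 2.85-fold with promoters of 1000 bp.

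**Figure D2:**
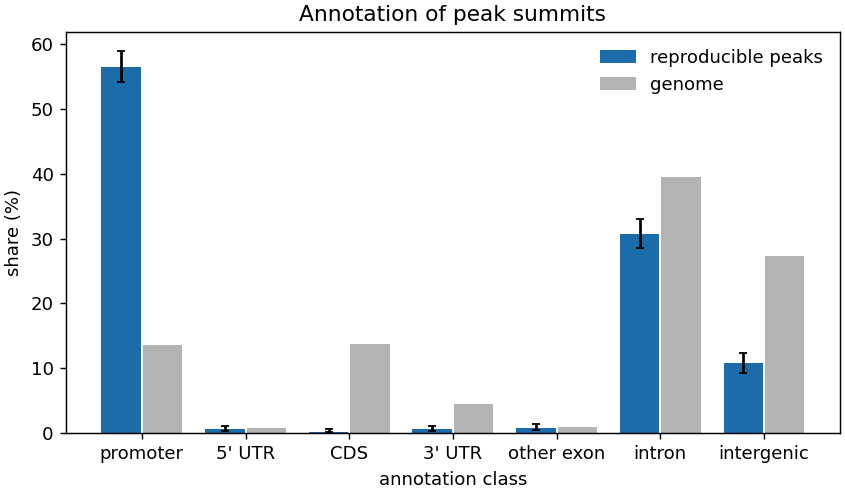
Share of reproducible peak summits in each annotation class (blue, with 95% Wilson intervals, n = 1664) beside the share of the genome in that class (grey). Promoters hold 56.6% of summits and 13.6% of the genome, and coding sequence 0.18% against 13.7%.

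Promoter peaks were slightly stronger than the others. Their mean log2 signal was 6.43 ± 0.66 (SD, 941 peaks) and that of the other 723 peaks 6.36 ± 0.62, a difference of 0.06 (two-sided permutation p = 0.039). Median signals were 77.4 and 72.9. Peaks at CG14100, Chro and Ugalt belong to the promoter class, whereas those at cbt, Lk6 and ph-p fell in introns between 509 and 1379 bp from the nearest TSS. The difference was 0.00 (permutation p = 0.972) with promoters limited to 200 bp and 0.03 (p = 0.289) with the strongest regions of replicate 2 alone. It was 0.13 with promoters of 1000 bp and 0.15 with replicate 1 alone.

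Peak density differed from that expected by arm length on 2L and on 4. Arm 2L, which holds ab and cbt, carried 344 peaks, or 14.6 per Mb, 1.18-fold its share of the genome (adjusted p = 0.0068, exact binomial over 6 arms). Chromosome 4, which holds PlexA, carried 6 peaks, or 4.45 per Mb and 0.358-fold (exact adjusted p = 0.013). On X, with Raf, kirre, Hr4 and ph-p, there were 308 peaks, 18.5% of the list against 17.6% of the length (1.05-fold, exact adjusted p = 0.477). The arms 2R (307 peaks), 3L (315) and 3R (384) did not pass after adjustment, with exact adjusted p of 0.684, 0.0757 and 0.486. Against the weakest regions of the pooled list the X share was 1.29-fold (Fisher's exact adjusted p = 7.2e-05). In the strongest regions of replicate 1 it was 1.16-fold (exact adjusted p = 0.025) and in those of replicate 2 0.971-fold (adjusted p = 0.606), so the direction on X depended on the replicate used. These alternatives were examined for X alone. Whether the differences on 2L and 4 depend on the replicate or on the background is therefore unknown.

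Among 11 lists of genes, cytosolic ribosomal proteins stood out. Of 92 ribosomal protein genes 32 (34.8%) had a peak, against 8.01 in random sets matched on length (95% of sets 3 to 14), a 3.99-fold excess (permutation adjusted p = 0.00022). The peaks lay at promoters for 31 of the 32, and at 22 of the 25 genes that were also nearest to the peak the summit was within 100 bp of the TSS. The strongest were at RpS27 (3R, 25247421 to 25247649, signal 181.3), RpL7 (2L, 10200939 to 10201102, 163.8) and RpS20 (3R, 20821768 to 20822277, 154.7). In replicates 1 and 2 their signals were 83.6 and 104.1, 70.9 and 92.3, and 81.5 and 71.3. RpS14a and RpS14b, neighbouring copies, shared 1 peak, so the 32 genes had 31 distinct peaks. Outside promoters, a setting chosen after seeing the data, 1 of the 92 genes had a peak against 0.525 by chance, too few to test, and over the other 10 alternatives the permutation adjusted p ran from 7.3e-05 to 0.0051.

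The list of Hippo, JAK-STAT and cell polarity genes, which control tissue growth and epithelial organisation, had peaks at 14 of 25 members against 5.57 by chance (2.51-fold, permutation adjusted p = 0.0016). In 8 of them the strongest peak was intronic. The strongest were at dlg1, a junctional scaffold (X, 11390730 to 11390880, signal 118.2), at Diap1, an inhibitor of apoptosis (3L, 16045983 to 16046492, 106.5), and at kibra (3R, 14722171 to 14722680, 97.1). The Hippo kinases hpo (61.5) and wts (67.9), their effector yki (70.9) and the transcription factor Stat92E (69.1) also had peaks. The nearest TSS to the peak counted for yki was that of Gpat4, 97 bp away. With the 832 peaks above the median signal the permutation adjusted p was 0.0648 at 2.49-fold, and with the strongest regions of replicate 2 alone it was 0.0802 at 1.88-fold. Over all 11 alternatives the permutation adjusted p ran from 7.3e-05, without matching on length, to 0.0852, with replicate 2 alone and no ab.

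Members of 2 lists were found less often than chance. Of 119 odorant and gustatory receptor genes, Or88a (signal 62.0) and Or85f (56.6) had a peak, against 12.0 by chance (0.166-fold, permutation adjusted p = 0.0016). Both peaks lay nearest to the TSS of another gene, CG12402 for Or88a and CG34117 for Or85f. None of the 29 neural precursor and neuron fate transcription factors, among them ac, sc, ase, pros and dpn, had a peak, against 4.77 by chance (permutation adjusted p = 0.023). With nearest-TSS assignment neither list passed, with permutation adjusted p of 0.11 for the receptors and 0.407 for the neural factors. The receptors also did not pass among genes with a relaxed region, which 34 of the 119 have (2 with a peak, 0.327-fold, permutation adjusted p = 0.151), a setting chosen after seeing the data. Without promoter peaks chance gives 0.813 receptor genes and 1.77 neural factors, too few to test a lower count. Over the other 10 alternatives the adjusted p ran from 7.3e-05 to 0.151 for the receptors and from 0.0219 to 0.407 for the neural factors, which passed in 6 of them. These passes include both settings without ab, which is in neither list, so they nearly repeat the main run and replicate 2 alone.

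The other 7 lists did not pass the threshold. The ecdysone pathway, the steroid response of insects, had peaks at 13 of 30 genes against 7.23 (1.80-fold, permutation p = 0.028, adjusted p = 0.0623), among them the nuclear receptor genes Hr3 (2R, 10219950 to 10220206, signal 174.1), Hr4 (154.2), EcR (97.1) and usp (76.2), and ImpL2 (137.0). With the strongest regions of replicate 2 alone its permutation adjusted p was 0.0401 (1.87-fold), with those of replicate 1 alone 0.304 (1.48-fold), and without promoter peaks, a setting chosen after seeing the data, 0.006. With peaks within 1 kb of a TSS, 5 of 30 ecdysone genes had one (1.10-fold, permutation adjusted p = 1), so over all 11 alternatives it ran from 0.00049 to 1. BTB transcription factors, the family of ab, had peaks at 8 of 18 genes against 4.76 (1.68-fold, permutation adjusted p = 0.229). The gene ab is itself one of the 8, and without it the count was 7 of 17 (1.57-fold, permutation adjusted p = 0.398). The others included Trl (3L, 14759331 to 14759595, intronic, 241.0), mod(mdg4) (188.0), lola (125.7) and br (97.3). In replicate 2 alone that list reached 2.36-fold with a permutation adjusted p of 0.0099, and without ab 2.30-fold with 0.0243, whereas replicate 1 alone gave 1.65-fold with 0.292, in a range from 0.0054 to 1; both settings without ab were chosen after seeing the data. Without matching on length, by permutation, BTB genes (adjusted p = 0.0054), ecdysone genes (0.00049) and axon guidance genes (0.013) would have passed.

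Axon guidance and neural adhesion genes had peaks at 14 of 49 members against 13.4 by chance, the strongest at PlexA (86.6), dlp (82.4) and Ptp10D (77.5). Muscle and tendon genes had them at 9 of 36 against 8.71, led by mbc (156.1), sr (126.0) and mew (109.3). The nearest TSS to the peak counted for mbc was that of Nup98-96, 78 bp away. In the Notch pathway N (109.4), numb (84.3) and mam (79.7) had peaks, 3 of 20 against 3.36. Segmentation genes had peaks at 2 of 34 members, bcd (60.2) and nkd (57.6), against 6.24 (permutation adjusted p = 0.126). Antp (58.9) and hth (53.3) were the 2 of 12 Hox genes and cofactors with a peak, against 2.99. The permutation adjusted p was 1 for the axon guidance, muscle, Notch and Hox lists.

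**Figure D3:**
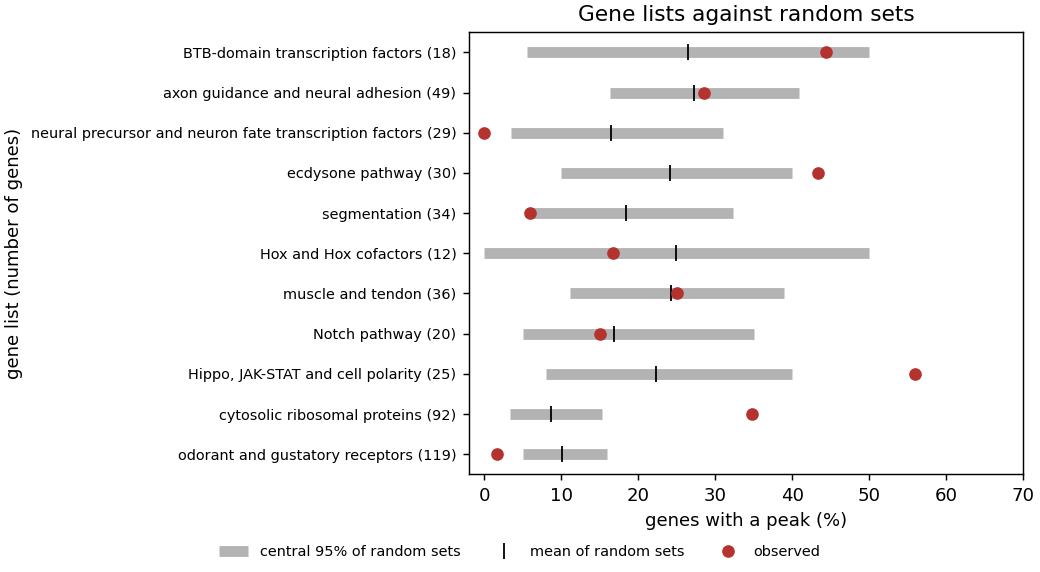
Percentage of genes with a reproducible peak in each of 11 lists (red points, list sizes in brackets) against 100000 random gene sets of the same lengths (black ticks, means; grey bars, central 95%). Ribosomal proteins (34.8%), the Hippo, JAK-STAT and polarity list (56%) and ecdysone genes (43.3%, not past the adjusted threshold) lie above the bars, receptors (1.68%) and neural factors (0%) below.

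The ab gene itself (2L, 11210678 to 11261080, plus strand) held 3 reproducible peaks, all intronic. Their positions were 11229165 to 11229674 (signal 102.8), 11220924 to 11221433 (64.7) and 11229396 to 11229905 (53.0). Of the 1394 genes in its decile of length, 64 had as many peaks or more. The signal came mainly from replicate 2, which gave 92.3, 55.7 and 49.8 at these peaks. Replicate 1 had 13.1 at the summit nearest to that of the peak from 11220924, where a further region of 20.9 overlapped the peak. It had no summit within 200 bp of those of the others, although a region of 10.3 (11228954 to 11229337) overlapped the peak from 11229165. In the strongest 1664 regions of each replicate, the ab territory held 7 of replicate 2 and 0 of replicate 1. Upstream of ab, between 11203537 and 11209566, lay 4 more reproducible peaks, outside the territory of ab, with pooled signals from 52.7 to 99.7. In that stretch replicate 1 had regions of 28.4 (11203601 to 11203984) and 28.0 (11209045 to 11209428), and replicate 2 reached 84.4. Both replicate 1 values lie above 24.7, the lowest among its strongest 1664 regions.

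**Figure D4:**
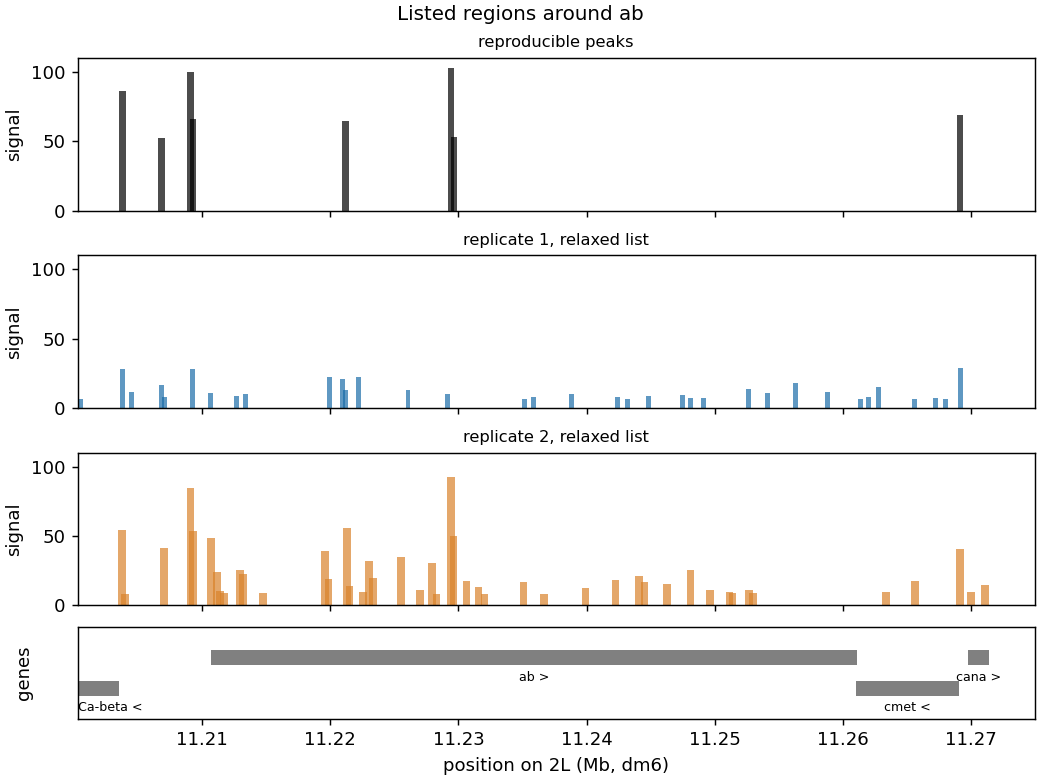
Regions around ab on 2L (x axis, Mb, dm6), with their signal as bar height, for the reproducible peaks (top), the relaxed lists of replicate 1 (blue) and replicate 2 (orange), and gene spans (grey, arrows giving the strand). Within ab replicate 1 reaches 22.6 and replicate 2 reaches 92.3.

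Sequence at the summits was compared with flanks of the same peaks. The DREF element TATCGATA, bound by a factor of housekeeping promoters, was present within 50 bp of the summit in 31 peaks and in the flank of 4 (adjusted p = 8.1e-06 over 7 motifs, exact McNemar). The GAGAG element of Trl was present in 190 at the summit and 299 in the flank (exact adjusted p = 7.3e-07), and the control TATAAA in 263 and 165 (adjusted p = 1.4e-06). Against positions of equal GC content DREF stayed higher (31 against 7, exact adjusted p = 0.00081), whereas GAGAG turned to 190 against 150 (adjusted p = 0.0521) and TATAAA was 263 against 256 (adjusted p = 1). Split by class, a setting chosen after seeing the data, 30 of the 31 peaks with DREF at the summit were at promoters. The GC-matched positions were not matched for promoters, so this control does not set DREF at these peaks apart from promoter sequence in general. In replicate 2 alone none of the 3 passed, with exact adjusted p of 0.615 for GAGAG, 0.206 for DREF and 0.453 for TATAAA. DREF also missed the threshold among peaks above the median signal (exact adjusted p = 0.115) and GAGAG with windows of 100 bp (0.362), in ranges over the alternatives from 1.1e-09 to 1 for DREF, 2.0e-06 to 0.615 for GAGAG and 6.6e-13 to 1 for TATAAA. The Zelda site CAGGTA (33 and 32 peaks), the E-box CANNTG (642 and 666), the nuclear receptor site AGGTCA (34 and 40) and the Hox-like control TAATTA (113 and 94) did not pass against the flank, with exact adjusted p from 0.321 to 1. TAATTA passed with replicate 1 alone (1.49-fold, exact adjusted p = 0.0073) and with windows of 100 bp (1.27-fold, 0.034), and was lower than at GC-matched positions (0.715-fold, 0.015).

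Of all 6-mers, counted on either strand, 275 were more frequent at summits than in the flanks and 327 less frequent at an adjusted p below 0.05. The mean GC content was 38.1 ± 8.63% (SD, 1664 peaks) at summits and 43.9 ± 8.29% in the flanks, and against GC-matched positions 58 were more and 44 less frequent. ACAGTG (CACTGT on the other strand) had the smallest p, with 207 peaks (12.4%) at the summit and 76 (4.57%) in the flank, 2.72-fold (exact McNemar adjusted p = 3.3e-14). It was followed by AAATAT (1.74-fold), TTTAAA (1.95-fold), ATATTA (2.02-fold), TTACAA (2.20-fold), TTAAAA (1.56-fold), ACTGTA (2.45-fold), ACACTG (2.28-fold), AACTAT (2.21-fold) and ATGTTA (2.48-fold). Against GC-matched positions AAATAT (1.06-fold), TTTAAA (1.30-fold), ATATTA (1.17-fold), TTACAA (1.10-fold) and ATGTTA (1.08-fold) did not pass, with exact adjusted p from 0.0505 to 0.835, and in replicate 2 alone ATATTA did not (1.27-fold, exact adjusted p = 0.193). Of these words ACTGTA and ACACTG overlap ACAGTG in sequence. Among the 941 promoter peaks 113 (12.0%) carried ACAGTG within 50 bp of the summit, 2.46-fold the flank. Among the 723 other peaks 94 (13.0%) did, 3.13-fold the flank, and both settings were chosen after seeing the data. These 94 include the peak of Lk6 (3R, 11760872 to 11761203), where the sequence GCATAGTTTTACAGTGGCACATAAAC stands at 11761019 to 11761044. With the strongest regions of replicate 2 alone the number of more frequent 6-mers was 50, and ACAGTG was at 2.25-fold (exact adjusted p = 2.2e-08).

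**Figure D5:**
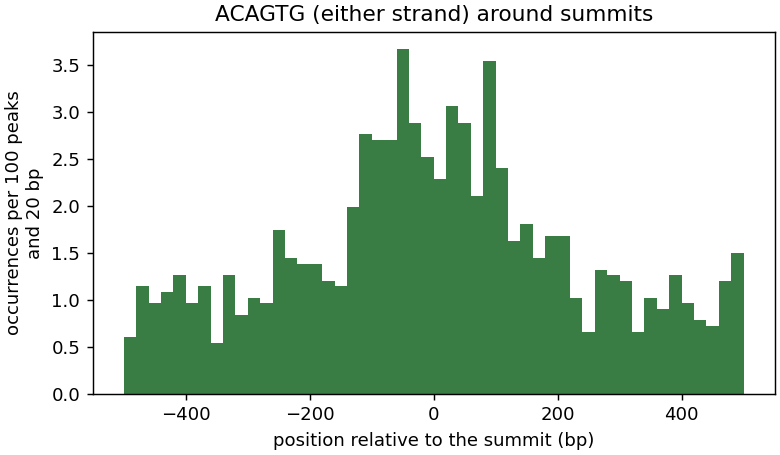
Occurrences of ACAGTG on either strand per 100 reproducible peaks in bins of 20 bp (y axis) against the distance from the summit in bp (x axis), n = 1664 peaks. Values are raised on both sides of the summit without a maximum on it, with 2.52 and 2.28 per 100 peaks in the bins that meet there, 3.67 in the bin starting 60 bp before and 3.55 in that starting 80 bp after, and lie between 0.541 and 1.502 in the bins more than 300 bp from it.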

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

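Signal appeared on sequences that enter no comparison above. On dm6, the relaxed list of replicate 1 held 4 regions on the Y chromosome, which is outside the arms compared, and those of replicate 2 and of the pool held 0; as the replicate lists end at a fixed number of regions and depths are unknown, this shows no difference between replicates. The strongest of the 4 had a signal of 8.08 and rank 17920 of 30000. On dm3, regions on heterochromatic or unplaced sequences numbered 446 in replicate 1 (1.70% of its list), 33 in replicate 2 (0.11%) and 44 in the pooled list (0.238%). None was among the reproducible peaks of dm3. In replicate 1 the strongest of the 446 had a signal of 29.2, and their median of 8.26 lay below the 9.09 of its other regions.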

How the results depend on the processing

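Of the alternatives, genes with a relaxed region, gene lists without promoter peaks, motifs at peaks outside or in promoters, 50 length bins, lists without ab and replicates matched directly were chosen only after results were seen. Over 27 results, 215 alternatives were run: 145 kept direction and side of the threshold or, for counts, stayed within 1.5-fold. A further 28 changed direction, whether or not either value passed the threshold, 20 lost and 12 gained a call, and 10 counts moved further. Settings without ab were also run for lists that do not hold ab, where they nearly repeat other settings. The promoter excess, the overlap of replicates and the correlation of their signals kept direction and side of the threshold in all alternatives run for them. The promoter excess stood at 3.92-fold and 4.24-fold with single replicates. The cause of the changes below was not tested.

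With single replicates the lowest and highest values were 0.971 and 1.16 for X, 0.0294 and 0.15 for promoter minus other log2 signal, 1.65 and 2.36 for BTB genes, 0.81 and 0.916 for axon guidance, 1.48 and 1.87 for ecdysone, 1.44 and 1.59 for Notch, 1.88 and 2.08 for the Hippo list, 0.305 and 0.681 for segmentation, 0 and 0.328 for Hox and 0.105 and 0.230 for receptors. They were 0 and 7 for peaks in ab, 50 and 349 for 6-mers more frequent at summits, 0.637 and 0.919 for GAGAG, 0.771 and 0.968 for the Zelda site, 2.18 and 2.64 for DREF, 1.16 and 1.57 for TATAAA and 1.08 and 1.49 for TAATTA.

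Against the weakest pooled regions X stood at 1.29, and with promoters of 200 bp the signal difference was 0.00114. Of the 11 gene lists 4 passed, and 2 passed with peaks above the median signal, with nearest-TSS assignment and without promoter peaks. With peaks above the median signal the folds were 0.516 for axon guidance, 0 for neural factors, 0.792 for muscle, 1.57 for Notch and 2.49 for the Hippo list. Within 1 kb of a TSS they were 0.497 for axon guidance, 0 for neural factors and 0.538 for muscle. With nearest-TSS assignment they were 0.285 for neural factors, 1.09 for segmentation, 1.16 for Notch and 0.262 for receptors. Without matching on length they were 3.36 for BTB genes, 2.16 for axon guidance, 0 for neural factors, 3.28 for ecdysone, 1.26 for Hox and 1.13 for Notch. Among genes with a relaxed region they were 0.992 for axon guidance, 0.991 for muscle and 0.327 for receptors, whose call was lost. Without promoter peaks they were 0 for neural factors and for receptors, 2.85 for ecdysone, 1.16 for Hox and for Notch and 1.90 for ribosomal proteins (1 gene, since their peaks are at promoters). With 50 length bins axon guidance stood at 0.964. With replicate 2 alone and no ab the folds were 2.30 for BTB genes, 0.918 for axon guidance, 1.87 for ecdysone, 1.60 for Notch and 1.88 for the Hippo list.

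The 275 6-mers more frequent at summits were 161 with peaks above the median signal, 58 against GC-matched positions, 140 outside and 98 in promoters. DREF was at 4.5 with peaks above the median signal. With windows of 100 bp GAGAG was at 0.943, the Zelda site at 0.825 and TAATTA at 1.27. Against GC-matched positions GAGAG was at 1.27, TATAAA at 1.03 and TAATTA at 0.715. The nuclear receptor site was at 1.25 outside promoters and the Zelda site at 0.9 in promoters. An IDR of 0.01 was not run, as no column gives it, and DREF outside promoters (1 summit and 0 flanks) gives no ratio. On dm3 the test of arms was not run, as it needs dm3 arm lengths, nor the count at ab, which needs a dm3 annotation. The dm3 list held 332 peaks (21.5%) on 2L, 6 (0.388%) on chromosome 4 and 285 (18.4%) on X. Read depth, unknown here, limits which weak regions could be listed.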

Other observations

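The 8 gene groups, the 48 words of 8 bases, the peaks far from starts, the comparison of ACAGTG by signal, that of ab with genes of as many peaks and all tests on replicate 2 at ab were chosen only after results were seen. Gene groups other than those fixed differed in how often they held peaks. Mitochondrial ribosomal protein genes had them at 14 of 73 members against 5.04 by chance (2.78-fold, permutation p = 0.00062, adjusted p = 0.005 over 8 groups), among them mRpS23, mRpS10 and mRpL41. Translation initiation factors (9 of 44 against 5.86, permutation adjusted p = 0.275) and proteasome subunits (6 of 48 against 4.39, adjusted p = 0.545) did not pass. Cuticle proteins (1 of 92 against 7.50, Cpr76Ba, permutation adjusted p = 0.018), ionotropic receptors (1 of 60 against 7.29, Ir60e, adjusted p = 0.018) and cytochrome P450 enzymes (3 of 85 against 10.1, adjusted p = 0.024) had fewer. Nuclear receptors, with Hr3, Hr4, Hr96, EcR, ERR and usp, had peaks at 8 of 21 against 4.87 (permutation adjusted p = 0.233), and the Osiris family at 0 of 25 against 2.88 (adjusted p = 0.141).

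More than 5 kb from any protein-coding TSS lay 31.2% of the 10688 weakest pooled regions and 254 reproducible peaks (15.3%). Starts of other genes were not counted in this distance. The peak nearest to eEF1gamma (signal 300.6), for example, is among the 254 but in the promoter class. Strong peaks among the 254 stood beyond CG4004 (X, 12751198 to 12751598, signal 407.5, 224.5 and 215.9 in replicates 1 and 2) and near CG13323 (2R, 13035206 to 13035501, intergenic, 362.3). Another stood 13956 bp downstream of a TSS of osa (3R, 17704264 to 17704566, in an exon outside coding sequence and UTRs, 336.8). Around ACAGTG, 48 words of 8 bases were tested. CACTGTGC, which is GCACAGTG on the other strand, stood at 55 summits and in 12 flanks, and CACTGTAC, or GTACAGTG, at 31 and 3. As all 48 hold ACAGTG, they were compared with it: the words made up 26.6% and 14.98% of its summit windows and 15.8% and 3.95% of its flank windows, and none of the 48 passed (lowest Fisher's exact adjusted p = 0.209). In 4 equal parts of the list by falling signal ACAGTG stood at 49, 52, 61 and 45 of 416 summits each, and peaks with it had a median signal of 73.9 against 75.2 without.

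For ACAGTG at summits, base composition was tested with GC-matched positions, where 12.4% of summit windows and 2.64% of matched windows held it, a ratio of 4.70 (exact McNemar adjusted p = 1.2e-24), which argues against composition as the whole cause. Choosing a 6-mer on the same peaks was tested by choosing on 2L and 2R, which gave TTAAAA and not ACAGTG; its ratio on the other arms was 1.44 (exact McNemar p = 6.3e-05), short of the bound of 1.5 set beforehand. Only after this was seen was weight given instead to the exact adjusted p of ACAGTG over all 6-mers, 3.3e-14. An element of any open promoter was tested on promoter regions among the weakest 10688 of the pooled list, of which 135 of 2306 held ACAGTG against 113 of 941 promoter peaks, a ratio of 2.05 (Fisher's exact p = 9.2e-09). At the 723 peaks outside promoters, a setting chosen after seeing the data, 94 summits (13.0%) and 30 flanks held it. That ratio of 3.13 (exact McNemar adjusted p = 8.3e-07) argues against a promoter element as the whole cause. As a hypothesis, ACAGTG may belong to a sequence recognised near these sites by the tagged protein or a partner, although it had no maximum on the summit (2.52 and 2.28 per 100 peaks in the bins beside it, 3.67 and 3.55 in bins farther out), and no biological explanation was tested, since the design has 1 group.

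For the peaks at ribosomal protein genes, pull-down of highly transcribed loci of every kind was tested on tRNA genes, of which 2.76% (8 of 290) had a summit within 500 bp against 8.44% of protein-coding genes (Fisher's exact p = 0.00014). Open promoters were tested among genes with a relaxed region, where the excess was 2.29-fold (permutation p = 2e-05, the smallest these sets can give). This does not decide on open promoters, since 8843 genes had such a region and having one does not measure how open a promoter is. With nearest-TSS assignment the excess was 5.04-fold (permutation p = 2e-05, again the smallest), which argues against peaks of neighbouring genes. The tRNA test leaves room, since tRNA copies share sequence and another polymerase reads them; snoRNA genes were also lower (6 of 269, 2.23%, Fisher's exact p = 4.7e-05), and 3 of 32 snRNA genes (9.38%, exact 95% interval 1.98 to 25.02%) had a summit. A candidate explanation that stays open is a pull-down at strong promoters unrelated to ab, as no untagged line was used here, and no biological explanation was tested.

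For the peaks inside ab, extra copies of the region in the tagged line were tested by the number of listed regions: the pooled relaxed list held 29, the 3 reproducible peaks included, in the 52403 bp of the ab territory, at percentile 99.69 of 10000 random windows (median 8), and replicates 1 and 2 held 24 and 36, at percentiles 98.5 and 99.1, past the bound first set. Binding would also bring weak regions, and of 63 other genes of like length with as many peaks or more 92.1% had fewer weak regions per kb than ab (26 regions or 0.496, reproducible peaks left out, against a median of 0.271), which missed the bound set for this second test and decided nothing. Signal of replicate 2 alone was first tested at the peak from 11220924. There 2.52% of 1590 matched peaks (95% Wilson interval 1.85 to 3.41%) had a lower log2 ratio of replicate 1 to replicate 2 than its -2.09. With the strongest region over each peak, a matching added after this was seen, the ratio was -1.41 and 6.32% of 1645 peaks lay lower (interval 5.24 to 7.60%). The replicate 1 region behind this ratio (20.9, 11220778 to 11221161) ended before the summit at 11221179, so these matchings leave the peak undecided. At the peak from 11229165 the ratio was -3.16 and 0.426% lay lower. A test of all ab peaks as 2 separate loci, chosen after the first missed its bound of 2.5%, found none with a summit among the strongest regions of replicate 1, with a chance of 0.0446 (exact hypergeometric; 0.0094 for 3 separate peaks), and may overstate the case, since it was found on these data. Extra copies, and signal of replicate 2 alone at both loci, stay open. The counts of regions do not tell copies from binding, and no biological explanation, such as binding of ab at its own gene, was tested.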
